A study of Mus musculus with 6 samples.

How the data were processed

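The series holds 6 bulk RNA-seq libraries of primary hepatic stellate cells from C57BL/6JBomTac mice, per the labels. Cells were cultured for 2 days and exposed for 3 h to 5 µM forskolin (3 libraries) or DMSO (3 libraries), and polyadenylated RNA was made into libraries with a kit that does not mark strand. The letters A, B and C in the labels gave the replicate names. The submitters' processing notes name the aligner STAR, the HOMER suite and the mm10 genome build, with no versions, order or settings. Duplicate handling, the counting rule and the annotation release are not given in the sources used here.

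The authors deposited 1 table of exon counts per gene, named as without adjustment. It has 24940 rows, 1 row per gene symbol, each with a RefSeq transcript, mm10 coordinates and a length. Values come in steps of 0.5, so the deposited expected counts were rounded to whole numbers (ties to the even number) before any count test. Of the RefSeq identifiers, 24772 were found in a GRCm38.p6 gene table. Gene types were read from the deposited annotation. Mitochondrial genes have no row, and 0 library columns lacked a sample. No near-identical copy in the genome was listed for any called gene. Depth, as the total of a column, ran from 2770629 to 10607997, so that 3 counts, used as the floor, equal 1.08 CPM in forskolin C and 0.283 CPM in forskolin B. Floors cover counting error only, since reads without molecular identifiers are not independent molecules.

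Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (12233 genes), libraries were scaled by TMM, and forskolin was compared with DMSO by the quasi-likelihood F test with robust dispersions. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and called at 0.05. CPM values use TMM-scaled library sizes, except that summed cell type markers, Alb, Pecam1 and Cdh5 are counts over column totals. Errors are SDs over 3 libraries or SEs of the fitted log2 fold change. These SEs are approximate: each is the absolute log2 fold change divided by the square root of its F statistic. The common biological coefficient of variation was 0.213. Adjusted p-values of single genes in the text are from edgeR unless another tool is named.

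Before the data were examined, 26 gene lists were fixed: cAMP/CREB targets, cAMP phosphodiesterases, adenylyl cyclases and cAMP effectors, Gs-coupled receptors, Gq- and Gi-coupled receptors, quiescent stellate cell markers, collagens and matrix assembly, contractile and actin genes, YAP/TAZ targets, TGF-beta pathway genes, matrix proteases, cytokines and NF-kB genes, interferon-stimulated genes, retinoid metabolism, growth factors, circadian clock genes, proliferation genes, cholesterol synthesis, lipid droplet and fasting genes, the unfolded protein response, and markers of 6 other cell types. The 22 lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The calls that held with an estimated correlation were those of the cAMP/CREB targets and the clock genes. Some members stand in more than 1 list, as Pde4b and Ctgf do.

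Named genes followed a rule fixed at the same time. It takes the 8 largest rises and 8 largest falls among called genes with at least 4 CPM on average and no overlap between the groups (7 predicted genes left out), and up to 4 called members per list by p. Where fewer than 2 members passed, it takes the 2 most abundant ones with their values, and it always takes Nr4a1, Crem, Pde4d, Acta2, Col1a1, Lrat, Pth1r and Vipr1. Genes outside this rule are said to be named after their values were seen, or are neighbours of a named gene; Egr1 and Alb, list members outside the rule, were also named after their values were seen. The value of 1 gene from the cholesterol list is not reported here.

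Other settings tried were RLE and upper quartile factors, library sizes alone, no filter, a filter of 1 CPM in 3 libraries, a filter of 10 CPM on average, DESeq2 1.42.0, limma-voom, the edgeR likelihood ratio test, the replicate letter as a block, each library left out in turn, an estimated correlation, fry, and lists without shared members. Added after the data were seen were a fit without both C libraries, limma-voom with sample quality weights, and offsets that follow abundance. The choice of a transcript for genes with several rows did not arise.

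The test was checked on simulated counts for the 12233 genes, drawn from the observed means and depths. Of 11947 genes kept there, the comparison recovered 57 of 99 genes changed 2-fold (57.6%) and 82 of 97 changed 4-fold (84.5%), with 7 unchanged genes called and 0 in the wrong direction. Camera called the 1 shifted list, whose members were all raised 2-fold, and 0 of 21 unshifted ones. List shifts under 2-fold were not simulated, though the median of every called list but the cAMP/CREB targets was under 2-fold. Genes were drawn independently, with the same dispersion in all libraries. The simulation therefore cannot show how the tests behave with correlated members, with estimates up to 0.42 in the data. Nor does it cover the larger spread of the C libraries reported below. Overlaps of named genes with other genes' exons were looked up in GENCODE mouse release 21 (GRCm38); Chd3os has no entry there. Overlaps over 10% of exon bases were on the opposite strand for Ctgf (23.2%), Gas1 (19.9%), Hand2 (19.6%), Gadd45a (19.1%), Gnas (13.1%) and Hsp90b1 (10.3%), and on the same strand for Trf (63.5%, with Gm20425) and Spp1 (18.8%), so reads of these genes and their partners cannot be separated there. Smaller overlaps were found for other named genes, Crem among them (8.01%).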

Results

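Gene expression was measured by RNA sequencing in mouse hepatic stellate cells, the vitamin A-storing pericytes of the liver sinusoid that turn into matrix-producing myofibroblasts in fibrosis. The cells were isolated from livers, kept in culture for 2 days and then given 5 µM forskolin or the solvent DMSO for 3 h. Forskolin is a plant diterpene that activates adenylyl cyclase directly and so raises the second messenger cAMP without a receptor ligand. Each group held 3 libraries, replicates A, B and C. The deposited table gave total counts of 9471384, 10607997 and 2770629 for forskolin A, B and C, and of 6753746, 9454833 and 3025990 for DMSO A, B and C. Both C libraries were thus the shallowest of their group. Log2 CPM of replicates A and B correlated at 0.980 across genes in the forskolin group and 0.972 in the DMSO group, while the pairs that included a C library lay between 0.925 and 0.930. Genes are not independent replicates, so these correlations only describe the libraries.

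The comparison asked which transcripts of stellate cells differ after 3 h of adenylyl cyclase activation. Forskolin raised 272 genes and lowered 70 of the 12233 genes tested, by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05. The risers included the 3 orphan nuclear receptor genes of the NR4A family. Nr4a1 went from 41.6 ± 0.839 to 455 ± 54.9 CPM (mean ± SD, n = 3 per group), a log2 fold change of 3.44 ± 0.13 (SE, adjusted p = 4.48e-07). Nr4a2 rose by 5.83 ± 0.31 and Nr4a3 by 4.76 ± 0.18 on the log2 scale. The fallers were fewer and changed less: the median log2 change was 1.33 among risers and −0.79 among fallers. At least a 2-fold change was seen for 185 risers and 22 fallers. Values of the 342 called genes did not overlap between the groups, against 2467 of all tested genes (20.2%, where chance gives 10%).

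**Figure D1:**
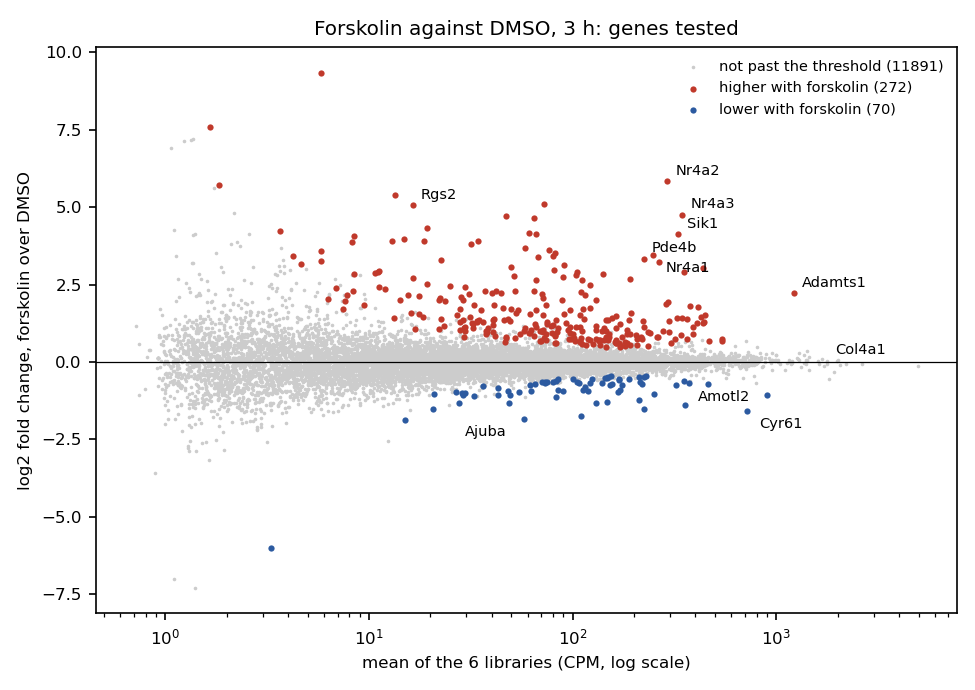
Fitted log2 fold change of forskolin over DMSO (vertical axis) against the mean of the 6 libraries in CPM (horizontal log axis) for the 12233 genes tested, with the 272 higher genes in red and the 70 lower genes in blue. Risers reach further from 0 than fallers at all levels above about 10 CPM; below that, folds of genes with no counts in a group depend on the fit's prior count and are not bounds.

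The largest rises among genes of at least 4 CPM, predicted genes left out, were in Crhbp, Nr4a2, Csf2rb2, Nap1l5, Rgs2, Nr4a3, Gja4 and AW011738. Crhbp, which encodes the binding protein of corticotropin-releasing hormone, had no count in any DMSO library and 11.6 ± 3.46 CPM with forskolin (n = 3). Against a floor of 3 counts in each DMSO library this is at least 19.4-fold higher. Rgs2, a GTPase activator that shortens Gq signalling, went from 1.08 ± 1.02 to 31.6 ± 8.06 CPM, and Gja4, the gap junction protein connexin 37, from 2.91 ± 2.54 to 91.3 ± 13.6 CPM. Nap1l5, a gene lying inside Herc3, rose by 5.10 ± 0.42 on the log2 scale, while Herc3 itself was at 0.01 (adjusted p = 0.997). Csf2rb2, a cytokine receptor chain with a close paralog next to it, Csf2rb, had 13 counts in DMSO B and none in the other two DMSO libraries. Its fitted log2 change of 5.40 ± 0.68 hangs on that library, without which no DMSO count remains; over all alternatives the change was at least 4.815 (adjusted p at most 0.00996). Csf2rb stood at 2.99 with an adjusted p of 0.168 by edgeR. How reads were divided between this pair is uncertain. AW011738, a noncoding gene at chromosome 4, 156203284 to 156206028 (mm10), adjoins Isg15 (156199424 to 156200818) and rose by 4.65 ± 0.29.

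Among genes of at least 4 CPM, the largest falls were in Chd3os, Ajuba, Adam19, Cyr61, Zfp955a, Bcar1, Amotl2 and Ifit2, also without predicted genes. Cyr61, a matricellular protein of the CCN family, went from 1072 ± 151 to 359 ± 28.9 CPM (log2 change −1.58 ± 0.15, adjusted p = 2.18e-04). Bcar1 (p130Cas, a scaffold of focal adhesions) fell by 1.53 ± 0.12 on the log2 scale, and Amotl2, an angiomotin that binds YAP, fell by 1.40 ± 0.11. Ajuba, a LIM protein that inhibits LATS kinases, fell by 1.85 ± 0.27 and the metalloprotease gene Adam19 by 1.74 ± 0.30. Zfp955a, a zinc finger gene, fell by 1.53 ± 0.24. Chd3os is noncoding and adjoins Chd3; it fell by 1.86 ± 0.39, and Chd3 was at −0.05 (adjusted p = 0.97). The library kit did not mark strand, so reads of such neighbours cannot be told apart where they overlap. Without 1 library at a time, 3 of these calls were lost. Adam19 had adjusted p = 0.0582 without forskolin A, 0.0628 without DMSO A and 0.0692 without DMSO B. Chd3os had 0.109 without forskolin B and 0.116, 0.18 and 0.0581 without DMSO A, B and C. Ifit2 had 0.11 and 0.0881 without forskolin A and B, and 0.0787 and 0.124 without DMSO A and B.

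Counts of calls moved with single libraries. The total of 342 was 189 without forskolin A, 207 without forskolin B, 203 without DMSO A and 185 without DMSO B, and the 70 fallers became 27, 27, 26 and 21. Without forskolin C, 485 genes were called, 113 of them lower. In a fit without both C libraries, added after the data were seen, 1229 genes were called, 738 higher and 491 lower, and all 342 genes of the 6-library fit were among them. The labels do not say whether replicates came from separate isolations or animals, so p-values measure only the spread between these samples, which may be technical.

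Target genes of cAMP and its transcription factor CREB were the list with the largest shift. Of 23 tested members, 18 rose, 1 fell and 4 did not pass (21 rose and 1 fell when adjusted over the list alone), with a median log2 change of 2.29. Sik1, a salt-inducible kinase, rose by 4.14 ± 0.17, from 35.0 ± 5.63 to 625 ± 99.3 CPM (n = 3 per group). Crem, the cAMP-responsive modulator gene that encodes the repressor ICER, rose by 3.53 ± 0.16. The member that fell was Egr1, an immediate-early gene driven mainly by ERK signalling, at −1.31 ± 0.11 (adjusted p = 8.9e-05). The set test camera placed the list above other genes (adjusted p = 3.23e-29), and the call held with an adjusted p = 0.00671 with an estimated correlation.

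Among cAMP phosphodiesterases, which degrade cAMP, 5 of 12 tested genes rose and none fell, both over all genes and adjusted over the list alone. Pde4b went from 40.7 ± 7.68 to 406 ± 73.2 CPM and Pde4d from 10.2 ± 3.56 to 89.6 ± 11.3 CPM (log2 changes 3.34 ± 0.17 and 3.07 ± 0.24, n = 3 per group). Pde10a rose by 2.23 ± 0.24 and Pde7b by 1.76 ± 0.25. Pde4b, Pde4d and Pde10a also stand in the cAMP/CREB list, so the calls on these lists are not independent. Camera gave adjusted p = 5.04e-06 for the list and adjusted p = 0.0602 with an estimated correlation. Of 23 tested adenylyl cyclases and cAMP effectors, 0 passed by edgeR in the main fit and 1 had an unadjusted p under 0.05. DESeq2, limma-voom and the likelihood ratio test each called 0. Without both C libraries 1 of 24 was called higher, and with sample quality weights 0. Gnas, the stimulatory G protein subunit, was at 0.19 ± 0.20 (adjusted p = 0.845) and Prkar1a, a regulatory subunit of protein kinase A, at 0.19 ± 0.13 (adjusted p = 0.681). The median of this list was −0.08 (camera adjusted p = 0.332).

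**Figure D2:**
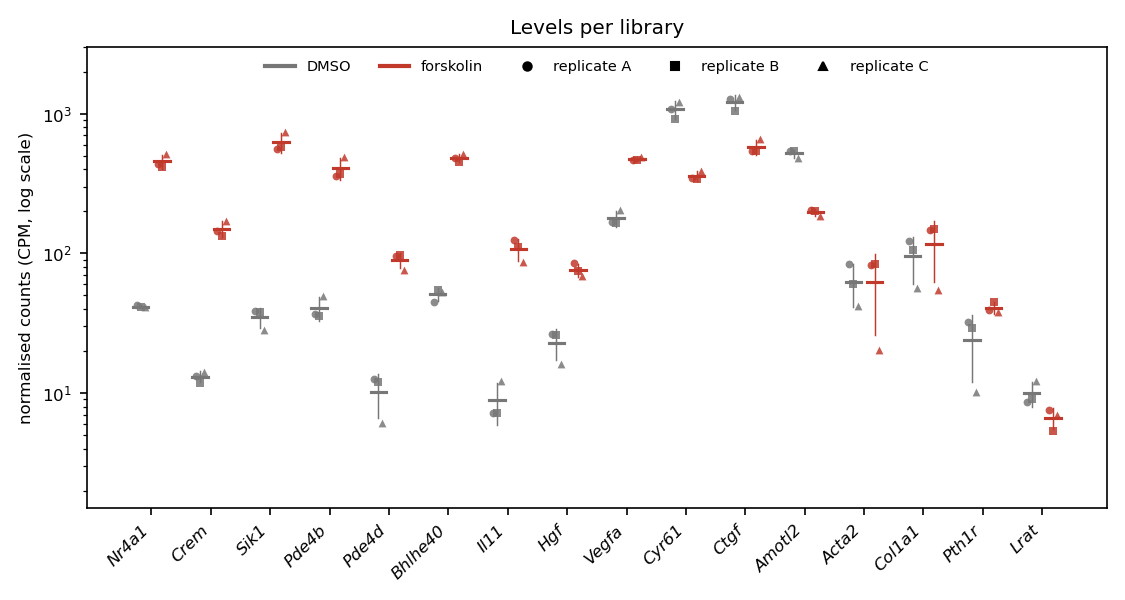
Normalised counts in CPM (vertical log axis) of 16 genes (horizontal axis) in each library, with DMSO in grey, forskolin in red, the replicate shown by the marker, a bar at the mean and a line of 1 SD to each side. All 3 forskolin libraries lie above the 3 DMSO libraries for the genes from Nr4a1 to Vegfa and below them for Cyr61, Ctgf and Amotl2, while the groups overlap for Acta2 and Col1a1 and stand apart without a call for Pth1r and Lrat.

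Receptors that couple to Gs, and so act through cAMP, showed no single call in the main fit. Without both C libraries 1 of 11 was called higher, and with sample quality weights 1. Of 10 tested in the main fit, 0 passed by edgeR, over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05. DESeq2 called 1, limma-voom 0 and the likelihood ratio test 2. The most abundant were Calcrl, the receptor of calcitonin gene-related peptide and adrenomedullin, at −0.11 ± 0.11, and Vipr1, a receptor of vasoactive intestinal peptide, at −0.16 ± 0.28 (44.5 ± 4.21 CPM in DMSO and 38.5 ± 16.0 with forskolin). The parathyroid hormone receptor gene Pth1r was at 24.0 ± 12.1 and 40.8 ± 3.81 CPM in DMSO and forskolin (log2 change 0.73 ± 0.33, adjusted p = 0.427). The list's median was 0.40 (camera adjusted p = 0.0175, and adjusted p = 0.3 with an estimated correlation). Of 15 receptors that couple to Gq or Gi, 3 rose and none fell, also when adjusted over the list alone. They were the sphingosine 1-phosphate receptor S1pr3 (1.32 ± 0.12) and the endothelin receptors Ednrb (0.75 ± 0.12) and Ednra (1.32 ± 0.25). Camera gave adjusted p = 0.00601 (adjusted p = 0.391 with an estimated correlation). Ednra had adjusted p of 0.1 and 0.106 without forskolin A and B, and 0.0854 and 0.0554 without DMSO A and B. The camera call on Gs receptors was lost without forskolin A (0.112), forskolin B (0.125, with the median at 0.2501) or DMSO C (0.0548), with no filter (0.0895) and at a filter of 10 CPM (0.15), and that on Gq and Gi receptors without DMSO C (0.247) or both C libraries (0.0627).

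Genes of the quiescent stellate cell gave few calls in the 6-library fit. Of 30 tested, 3 rose and 27 did not pass, over all genes and adjusted over the list alone. Hgf, hepatocyte growth factor, went from 22.9 ± 5.79 to 76.3 ± 8.04 CPM (log2 change 1.71 ± 0.20, n = 3 per group). The transcription factor gene Hand2 rose by 1.03 ± 0.19 and Gdf2, which encodes BMP9, by 1.16 ± 0.26. Lrat, the retinol esterifying enzyme, was low in both groups, at 9.94 ± 1.97 CPM in DMSO and 6.66 ± 1.14 CPM with forskolin (log2 change −0.57 ± 0.37, adjusted p = 0.647), with no overlap of values between the groups. The list's median was 0.11 (camera adjusted p = 0.0428, and adjusted p = 0.198 with an estimated correlation). That call was lost without forskolin A (0.0909), forskolin B (0.108), DMSO A (0.0685) or DMSO B (0.134), and with library sizes as the scaling (0.0635). Without both C libraries 8 of 30 were called higher and 0 lower (camera adjusted p = 0.00447), and with sample quality weights 5 and 0. Hand2 had adjusted p = 0.101 without forskolin A and 0.104 without DMSO B. For Gdf2 it was 0.256 and 0.214 without forskolin A and B, 0.207, 0.182 and 0.0594 without DMSO A, B and C, and 0.077 with library sizes as the scaling.

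Collagens and genes of matrix assembly gave no call in the main fit, as single genes or as a group. Of 27 tested, 0 passed by edgeR, over all genes or adjusted over the list alone; 1 had an unadjusted p under 0.05, and DESeq2, limma-voom and the likelihood ratio test called 1 each. Col4a1, a basement membrane collagen, was at 1741 ± 189 CPM in DMSO and 1801 ± 37.4 CPM with forskolin, and Col4a2 at 989 ± 176 and 1046 ± 151 CPM. Col1a1, the fibrillar collagen of scars, was at 95.2 ± 34.8 and 117 ± 53.8 CPM (log2 change 0.30 ± 0.35, adjusted p = 0.857). The median was 0.08 (camera adjusted p = 0.186, and 0.635 with an estimated correlation). Camera passed for this list without forskolin C (0.0047), without DMSO A (0.0202) and with the replicate letter as a block (0.0281). It also passed without both C libraries (0.0354), where 4 members were called higher and Col1a1 had adjusted p = 0.0137.

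Contractile and actin cytoskeleton genes gave 1 call in the 6-library fit. Of 23 tested, 1 fell and 22 did not pass, with the same count when adjusted over the list alone. Without both C libraries 4 of 24 were lower and 1 higher, and with sample quality weights 2 and 0. The member that fell was Lima1, an actin-bundling protein, from 176 ± 4.27 to 130 ± 0.874 CPM (log2 change −0.43 ± 0.10, adjusted p = 0.041). Acta2, smooth muscle actin and the usual marker of activated stellate cells, was at 62.3 ± 21.2 CPM in DMSO and 62.3 ± 36.5 CPM with forskolin. Its log2 change of 0.03 ± 0.41 turned negative without forskolin A (−0.19), forskolin B (−0.23) or DMSO C (−0.15). Myh9, nonmuscle myosin, was at −0.08 ± 0.18 and Flna, filamin A, at −0.06 ± 0.17. The median was −0.06 (camera adjusted p = 0.151). Lima1 had adjusted p of 0.204 and 0.192 without forskolin A and B, 0.167, 0.209 and 0.0657 without DMSO A, B and C, and 0.0636 with no filter.

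Target genes of the coactivators YAP and TAZ moved in both directions. Of 22 tested, 4 fell and 1 rose (4 and 3 when adjusted over the list alone); without both C libraries 5 were lower and 5 higher, and with sample quality weights 5 and 4. Cyr61, Ctgf, Amotl2 and Ankrd1 fell; Ctgf, connective tissue growth factor, went from 1209 ± 149 to 580 ± 72.6 CPM (log2 change −1.06 ± 0.16, n = 3 per group). Ankrd1 fell by 0.72 ± 0.13 on the log2 scale; it is named here after its value was seen. The member that rose was Gadd45a, a stress response gene, by 1.59 ± 0.19. Camera did not place the list apart (adjusted p = 0.317), and fry's mixed test, which asks for change in either direction, gave adjusted p = 2.04e-06. That mixed test also passed for lists with 1 called member, retinoid metabolism (0.00135) and proliferation (0.00504), but not for collagens (0.746) or contractile genes (0.495). A pass alone therefore does not set the YAP/TAZ list apart. Cyr61 and Ctgf were densely covered, at 2.31 and 2.47 reads per base on average, a range in which counts grew less than depth between libraries.

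TGF-beta pathway genes included 5 that rose and 1 that fell among 25 tested (8 and 1 when adjusted over the list alone, 9 and 2 without both C libraries). Smad6, an inhibitory Smad, rose by 1.56 ± 0.19, and the decoy receptor gene Bambi by 1.29 ± 0.15. The ligand gene Tgfb1 rose by 0.62 ± 0.10 and the Ski-like corepressor gene Skil by 0.65 ± 0.10; Id2 rose too, by 1.36, and Ctgf fell. Tgfb1 and Id2 are named after their values were seen. The median was 0.28 (camera adjusted p = 2.49e-04, and adjusted p = 0.0602 with an estimated correlation). Among matrix proteases and their inhibitors, 4 of 22 rose and none fell (7 and 0 adjusted over the list alone, 8 and 2 of 23 without both C libraries). Adamts1, an aggrecanase, went from 426 ± 20.1 to 2012 ± 438 CPM, and Adamts9 rose by 2.28 ± 0.26. The plasminogen activator genes Plat and Plau rose by 1.97 ± 0.27 and 1.28 ± 0.15. Camera gave adjusted p = 0.00831 (adjusted p = 0.3 with an estimated correlation), and 0.0996 without forskolin B or 0.0672 without DMSO C.

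Cytokines, chemokines and NF-kB genes held 9 risers and no faller among 22 tested (11 and 2 when adjusted over the list alone, 11 and 3 of 23 without both C libraries). The IL-6 family genes Il11 and Lif rose by 3.70 ± 0.24 and 3.14 ± 0.40, and the alarmin gene Il33 rose by 4.12 ± 0.47, from 6.23 ± 5.40 to 126 ± 12.7 CPM (n = 3 per group). Nfkbiz, a nuclear IkB protein, rose by 1.04 ± 0.14. Camera gave adjusted p = 5.04e-06 for the list and adjusted p = 0.172 with an estimated correlation. Growth factors and secreted ligands held 4 risers and no faller among 26 (6 and 0 adjusted over the list alone, 7 and 0 of 29 without both C libraries). Vegfa, the angiogenic factor, went from 178 ± 22.7 to 475 ± 15.8 CPM, and Bmp2 rose by 0.99 ± 0.14; Hgf was the third. Fgf18 had 7 counts over the DMSO libraries and 6.97 ± 3.36 CPM with forskolin (log2 change 4.23 ± 0.93, adjusted p = 0.0403). Its call did not hold without any 1 of the 6 libraries, with adjusted p of 0.071, 0.27 and 0.056 without forskolin A, B and C, and 0.0628, 0.2 and 0.0681 without DMSO A, B and C, nor by limma-voom (0.158) or with sample quality weights (0.087). Camera gave this list adjusted p = 0.00117, and adjusted p = 0.243 with an estimated correlation.

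**Figure D3:**
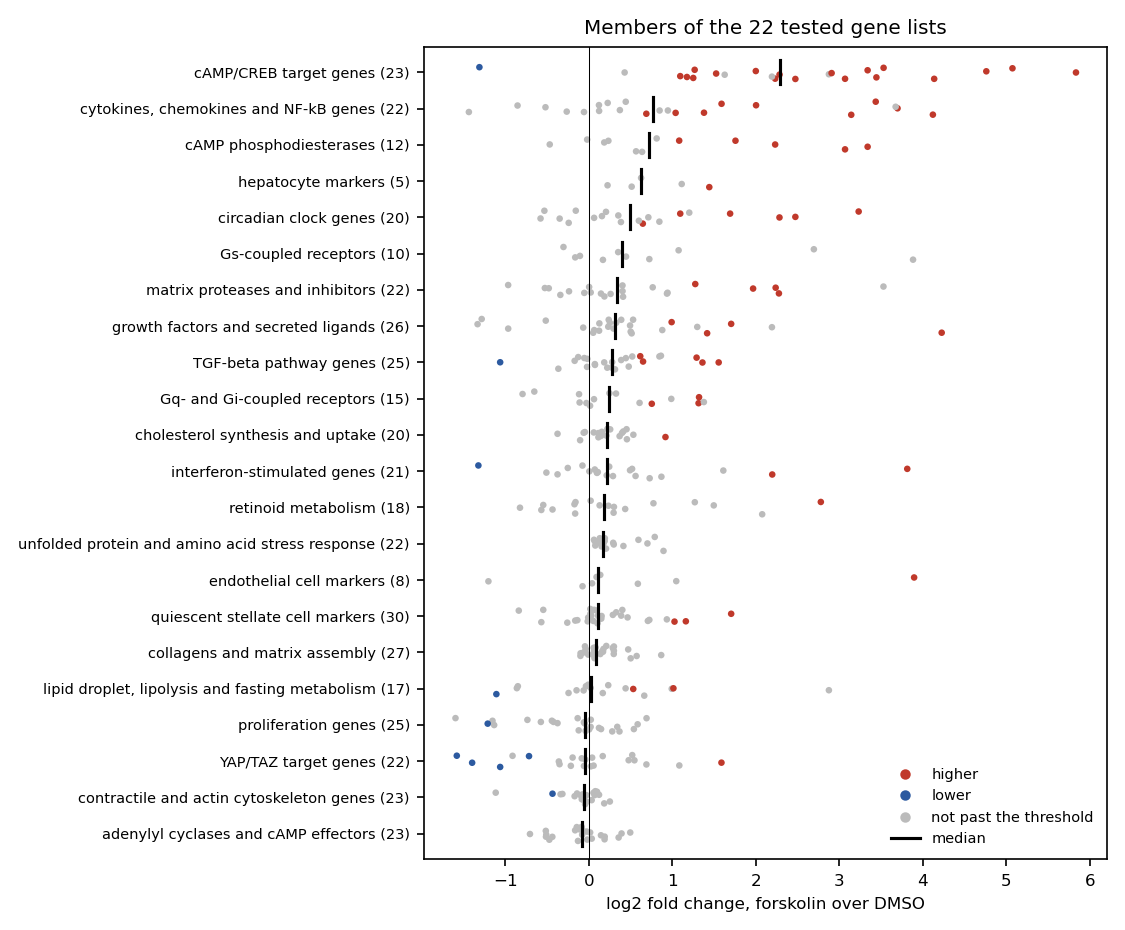
Log2 fold change of forskolin over DMSO (horizontal axis) for each tested member of the 22 gene lists with at least 5 tested members (vertical axis, number tested in brackets), with called risers in red, called fallers in blue, other members in grey and the median as a black line. The cAMP/CREB target genes have a median of 2.29, while the medians of the adenylyl cyclase, contractile, YAP/TAZ and proliferation lists lie slightly below 0.

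Circadian clock genes rose in part. Of 20 tested, 6 rose and none fell (9 and 1 when adjusted over the list alone, 7 and 2 without both C libraries), with a median log2 change of 0.49. Bhlhe40, a repressor of the clock, went from 51.0 ± 5.11 to 479 ± 31.1 CPM (log2 change 3.23 ± 0.13, n = 3 per group). Nfil3 rose by 2.47 ± 0.12, Per2 by 2.28 ± 0.20 and Cry2 by 1.69 ± 0.12. Nfil3 and Per1 also stand in the cAMP/CREB list. Camera gave adjusted p = 7.61e-07, and the call held with an adjusted p = 0.0458 with an estimated correlation.

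Hepatocyte, endothelial and other cell markers were checked for RNA of other liver cells. As counts over column totals, summed hepatocyte markers were 163 ± 16.7 CPM with forskolin and 101 ± 3.60 CPM in DMSO, mostly from Ass1 and Trf. Trf, the iron carrier transferrin, whose exons overlap the annotated gene Gm20425, rose by 1.44 ± 0.24, while Ass1 was at 0.51 ± 0.13 (adjusted p = 0.0918). Ass1 did pass as higher by limma-voom (0.0174) and the likelihood ratio test (0.015), with no filter (0.0373), without forskolin C (0.0362), without both C libraries (0.00024) and with sample quality weights (0.00104). The albumin gene Alb, abundant in hepatocytes, was on the scale of the sums at 5.23 ± 3.17 CPM with forskolin and 4.43 ± 1.51 CPM in DMSO. Of 5 tested hepatocyte markers, 1 rose (2 adjusted over the list alone), and camera gave adjusted p = 0.00384 (adjusted p = 0.103 with an estimated correlation). Trf had adjusted p of 0.0621 and 0.0602 without forskolin A and B, and 0.056 without DMSO B. Of 8 endothelial markers, 1 rose, also when adjusted over the list alone: Egfl7, from 3.66 ± 3.46 to 64.6 ± 15.3 CPM. Esam and Plvap were at 0.04 ± 0.14 and 0.09 ± 0.12 (camera adjusted p = 0.328 for the list). Summed endothelial markers were 348 ± 62.3 CPM with forskolin and 281 ± 10.8 CPM in DMSO, mostly from Esam and Plvap. Most of the difference came from Egfl7. On the same scale Pecam1 was at 3.88 ± 0.528 CPM with forskolin and 4.17 ± 1.7 CPM in DMSO, and Cdh5 at 0.576 ± 0.581 and 1.99 ± 1.98 CPM. Pecam1 and Cdh5 are named after their values were seen.

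Other cell types gave lower sums. Markers of Kupffer cells and macrophages summed to 23.6 ± 3.10 CPM with forskolin and 27.5 ± 4.0 CPM in DMSO, those of cholangiocytes to 31.1 ± 19.2 and 18.6 ± 3.26 CPM, those of lymphocytes to 7.57 ± 0.477 and 10.2 ± 1.91 CPM, and those of portal fibroblasts and mesothelium to 80.1 ± 13.7 and 67.7 ± 5.82 CPM. In each of these 4 lists 3 genes were tested and 0 passed by edgeR in the main fit, DESeq2, limma-voom or the likelihood ratio test, with 1 portal fibroblast gene and no other at an unadjusted p under 0.05. The 2 most abundant members of each were at log2 changes of −0.33 ± 0.31 (Cd68) and 0.77 ± 0.46 (Cd14), 1.22 ± 0.60 (Spp1) and 0.96 ± 1.42 (Sox9), 0.50 ± 0.75 (Cd79a) and −1.44 ± 0.96 (Ccl5), and 0.53 ± 0.23 (Gas1) and −0.07 ± 0.20 (Efemp1). Other fits called some members higher: Spp1 with no filter (0.00661), without both C libraries (0.002) and with sample quality weights (0.046), Gas1 without both C libraries (0.00558) and with weights (0.0126), and the cholangiocyte marker Sox9 without both C libraries (0.00298). In that last fit 2 of 5 cholangiocyte markers and 1 of 4 of portal fibroblasts and mesothelium were higher.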

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

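The test of male origin was chosen after the result was seen. The labels describe the donor mice as female, but the Y-linked gene Ddx3y was counted in every library. It was also among the called risers, at a log2 change of 0.50 ± 0.10 (edgeR adjusted p = 0.0225), from 120 ± 3.18 to 170 ± 3.95 CPM (mean ± SD, n = 3 per group). Ddx3y had 1635, 1866 and 425.5 counts in forskolin A, B and C and 802.5, 1215.5 and 358 counts in DMSO A, B and C, above the 3 counts taken as the floor. The X inactivation transcript Xist, abundant in female cells, had 0 to 16.5 counts. A count on Y-linked genes could come from reads of their X-linked homologs, but over 4 gene pairs (Ddx3y, Kdm5d, Uty and Eif2s3y against their X partners) and 6 libraries the median ratio was 0.273, and pair medians ran from 0.116 to 0.503, above the 0.1 set as the bound for stray reads. Cells of male origin remain a candidate explanation. All 6 libraries had the 4 Y-linked genes above the floor (lowest count 40) and Xist at or under 1.36% of Ddx3y. These values argue against female cells, the sex given in the labels, as the source of these 6 libraries. No biological explanation by the study's groups was tested, since both groups show it.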

How the results depend on the processing

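The fits without both C libraries, with sample quality weights and with abundance-dependent offsets were chosen after the data were seen. All 342 called genes kept their direction under every alternative that tested them. This was largely fixed in advance, since their values did not overlap between the groups, so it is no separate support. Of 60 called named genes 49 also stayed past the threshold throughout. Most were picked by size of change or p-value in these data, so that share does not stand for all calls. Of the 342 calls, 187, 206 and 333 were kept without forskolin A, B and C. Without DMSO A, B and C, 201, 183 and 274 were kept. Depth limits genes near 1 CPM in the C libraries. Across scalings the median of all genes lay between −0.0329 and 0.006 on the log2 scale.

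Totals of changed, higher and lower genes were 620, 463 and 157 without a filter and 648, 458 and 190 by the edgeR likelihood ratio test, which also called 319 genes at 2-fold. DESeq2 and limma-voom called 109 and 125 lower genes, and 479 and 482 in all. Without both C libraries they were 1229, 738 and 491, with 383 at 2-fold, and with sample quality weights 984, 595 and 389, with 345 at 2-fold. Leaving out 1 library gave 185 to 485 changed, 162 to 372 higher and 21 to 113 lower genes; fits with fewer libraries have fewer degrees of freedom. The rise without both C libraries was tested in the closing section, and the cause of the other changes was not.

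The letters were not taken as pairs, since the labels do not link samples by letter and not every same-letter correlation was over 0.1. Deviations from the group means correlated at 0.0476 for A, 0.133 for B and 0.15 for C, and forskolin A correlated better with DMSO B (0.103). Each C library correlated negatively with A and B of the other group, from −0.147 to −0.0797. Deviations cancel out within a group, so the values of A and B also carry what C does. A deviation shared by both C libraries stays in the error of the main fit. Col1a1 had one, at 54.4 and 56.3 CPM in forskolin C and DMSO C and 106 to 149 CPM in the A and B libraries. Vipr1 did not, at 20.2 CPM in forskolin C and 47.4 CPM in DMSO C. How many genes share such a deviation was not counted. With the replicate letter as a block, 649 genes were called (455 higher, 194 lower) and collagens passed camera with a median of 0.0892 (adjusted p = 0.0281). Spp1 (0.0235) and Ass1 (0.05, rounded) passed there too, and Fgf18 lost its call (0.0596).

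Lists called fell from 14 to 2 with an estimated correlation and to 8 with fry. For some lists that lost camera's call, a correlation above the preset 0.01 is argued against as the cause. Their estimates were −0.00525 for TGF-beta, 0.00923 for quiescent, −0.0142 for interferon, −0.0262 for cholesterol, −0.00696 for unfolded protein and −0.149 for hepatocyte genes. The other lists that lost it had estimates of 0.0255 (phosphodiesterases) to 0.42 (Gq and Gi receptors). The cAMP/CREB and clock lists kept the call, with estimates of 0.00833 and −0.0267, both under the preset. Their unadjusted camera p still rose, from 1.47e-30 to 0.000305 and from 6.92e-08 to 0.00416. A higher correlation therefore cannot account for the rise in p in these lists. The quiescent list, at a median of 0.11, lost its camera call with an estimated correlation (0.198), and at 0.0726 with library sizes alone (0.0635). It did not pass fry either (0.126), which tests a list against no change and not against other genes. Without 1 library its median was 0.0959 to 0.171 and its adjusted p 0.0127 to 0.134; for collagens the ranges were 0.0393 to 0.296 and 0.0047 to 0.942. Without both C libraries collagens passed at a median of 0.132 (0.0354). Medians ran from 0.25 to 0.534 for Gs receptors, −0.122 to −0.00807 for cyclases and effectors and −0.0707 to −0.00635 for contractile genes without 1 library. The cause of these changes was not tested further.

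Some values changed sign. The lipid list went to −0.00595 with upper quartile factors, −0.0172 with library sizes, −0.00354 with abundance offsets and −0.0205 without shared members, as did Plin2 with the first 3 of these (−0.00595, −0.0172 and −0.00354). Proliferation went to 0.00602 at 10 CPM and 0.00135 without both C libraries. Plin2 was at −0.0121, Col4a1 at −0.0189, Hspa5 at −0.0226, Hsp90b1 at −0.0248 and Vipr1 at 0.138 without both C libraries. With weights Plin2 was at −0.00445, Hsp90b1 at −0.0137 and Vipr1 at 0.0759, and Acta2 at −0.0636 with the block. Over fits without 1 library, values ran from −0.23 to 0.398 for Acta2, −0.00869 to 0.146 for Col4a1, −0.0525 to 0.203 for Col4a2, −0.0375 to 0.172 for Esam, −0.0479 to 0.344 for Gnas, −0.171 to 0.231 for Hsp90b1, −0.245 to 0.382 for Hspa5, −0.0101 to 0.57 for Pcna, −0.0405 to 0.0682 for Plin2, −0.382 to 0.107 for Vipr1, −0.111 to 0.0524 for the YAP/TAZ list, −0.0193 to 0.141 for the lipid list and −0.0193 to 0.383 for the retinoid list. No longest-transcript alternative could be run, since each gene has 1 row.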

Other observations

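No test in this part was chosen after its result was seen, but the fit without both C libraries, which raised the question of their depth and spread, the pattern in densely covered genes and the genes named in the next paragraph were chosen after the data were seen. For the rising genes with ATTTA pentamers, the threshold written beforehand was an unadjusted p under 0.05, which their result met, and the stricter reading by adjusted p was set after it was seen.

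After 3 h of forskolin the AP-1 genes Fos, Fosb and Fosl2 rose by 2.28 ± 0.20, 2.0 ± 0.18 and 1.28 ± 0.12 on the log2 scale, and Jun was at −0.16 ± 0.13 (edgeR adjusted p = 0.737). Dusp1, a MAP kinase phosphatase, rose by 1.25 ± 0.18, while Dusp6, a phosphatase induced by ERK, fell by 0.94 ± 0.14 and Egr1 by 1.31 ± 0.11. Klf4, a Krüppel-like factor, went from 94.4 ± 20.5 to 782 ± 120 CPM, and Cebpd from 30.3 ± 6.07 to 192 ± 24.7 CPM (mean ± SD, n = 3 per group). Among genes outside the fixed lists, Kcne4, a potassium channel subunit, rose by 2.84 ± 0.11, Star, which carries cholesterol into mitochondria, by 2.68 ± 0.15 and Hilpda, a lipid droplet protein, by 2.81 ± 0.14. The cholesterol exporter gene Abca1 rose by 3.42 ± 0.41.

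Interferon-stimulated genes held 2 risers and 1 faller among 21 tested (3 and 1 when adjusted over the list alone). Rsad2 rose by 3.81 ± 0.28 and Isg15 by 2.20 ± 0.20, while Ifit2 fell by 1.32 ± 0.25 (camera adjusted p = 0.0124, adjusted p = 0.114 with an estimated correlation and 0.0588 without both C libraries). In retinoid metabolism 1 of 18 rose (2 over the list alone, 4 without both C libraries): Dgat1, which also makes triglyceride, by 2.78 ± 0.30, with Plin2 at 0.02 ± 0.11, Rxra at −0.16 ± 0.11 and camera at adjusted p = 0.363. Of 17 lipid droplet and fasting genes, 2 rose and 1 fell (4 and 1 over the list alone). Irs2 and Cpt1a rose by 1.01 ± 0.11 and 0.53 ± 0.11, and Pdk4 fell by 1.11 ± 0.20 (camera adjusted p = 0.186). Of 20 cholesterol genes 1 rose (2 over the list alone, 5 without both C libraries), Insig1 by 0.92 ± 0.13 (camera adjusted p = 0.00733, and adjusted p = 0.103 with an estimated correlation). Of 25 proliferation genes 1 fell (2 over the list alone), Myc by 1.21 ± 0.12, with Pcna at 0.34 ± 0.26 (camera adjusted p = 0.21). Of 22 genes of the unfolded protein response, 0 passed by edgeR in the main fit (3 higher over the list alone, 5 without both C libraries and 3 with sample quality weights), 3 had an unadjusted p under 0.05, and DESeq2, limma-voom and the likelihood ratio test called 2, 2 and 3. Hspa5 was at 0.15 ± 0.29 and Hsp90b1 at 0.08 ± 0.22 (camera adjusted p = 0.0025, and adjusted p = 0.0925 with an estimated correlation). Without 1 library, calls were lost for Pdk4 (0.0769 without forskolin B, 0.0817 without DMSO A) and for Cpt1a (0.132 and 0.131 without forskolin A and B, 0.154, 0.0533 and 0.0696 without DMSO A, B and C), and Cpt1a also lost it with library sizes as the scaling (0.075).

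Of the 10 splits of the 6 libraries into 3 and 3, the split by treatment called 342 genes and the highest of the other splits called 0, so 1 split reached the count. With 10 splits no share under 0.05 can arise.

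Leaving out both C libraries raised the count of changed genes from 342 to 1229, although 2 libraries per group remained. Lower depth of C alone is argued against: with the A and B libraries thinned to 2770454 counts each, 1121 genes were called (median of 10 draws, 973 to 1157), above the bound of 513. A larger spread of the C libraries beyond counting error is consistent with the data. At equal depth, the squared difference over the sum of counts of 6297 genes at 20 to 200 CPM was at least 2.5 times that between A and B in the DMSO group and at least 4.22 times in the forskolin group. This ratio is relative, so it cannot tell C libraries that stray from A and B libraries that are unusually alike. What made C differ from A and B stays open, since the labels give no batch, input amount or RNA quality.

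Counts of densely covered genes grew less than depth. The log2 ratio of A plus B to C in the forskolin group was 3.21 for genes under 0.05 reads per base and 2.15 for the 74 genes at 2 or more, and in the DMSO group 2.68 and 1.89. If all abundant genes were truly higher in the shallow libraries, gene length should not matter at a given CPM, but among 1251 genes of at least 200 CPM the coefficient per doubling of length was 0.142 ± 0.00827 (SE) in DMSO and 0.231 ± 0.00845 in forskolin, where a bound of 0.02 was set. Saturation of read positions is a candidate explanation: these coefficients exceeded those of genes at 10 to 50 CPM by 0.0938 ± 0.0129 and 0.153 ± 0.0137. Whether duplicate reads were removed is not given in the sources used here, and a length bias of RNA quality in the C libraries was not tested apart.

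A hypothesis was that genes moving within 3 h have short-lived mRNAs, read from ATTTA pentamers per kilobase of 3' UTR and set against unchanged genes matched on CPM and 3' UTR length (10000 draws, one-sided permutation tests, 2 tests). Of the fallers, 67 of 70 had a 3' UTR, with a median of 1.61 per kilobase against 1.6 in matched sets (95% of draws 1.19 to 2.04, permutation p = 0.463, adjusted p = 0.463). No excess was found, and one within that range would not have been seen. Of the risers, 261 of 272 had a 3' UTR, with a median of 1.72 against 1.49 (1.28 to 1.74, permutation p = 0.0292), which did not pass after adjustment (adjusted p = 0.0584). On simulated sets the test recovered 1 of 1 enriched set and called 0 of 10 random ones.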
